A study of Homo sapiens with 6 samples.

How the data were processed

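RNA sequencing was carried out on 6 libraries of PC3 cells, 3 treated with MYCi361 at 6 µM for 24 h and 3 with DMSO, per the labels' protocols. Libraries were made from 50 ng of total RNA with a strand-specific kit that enriches coding RNA by capture probes (TruSeq RNA Access), per the labels' protocols, so transcripts without probes are measured poorly. The submitters' processing notes name cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2, and the genome builds hg19 and mm10, without their roles. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited a table per library with raw, whole-number counts for 25369 gene symbols, in the same order in each. The symbols are used as the files give them, and no coordinates are given because the reference at hand is on another build (GRCh38). No column of a sample outside the series was present (0 columns).

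Samples were grouped by their titles, which carry the treatment and a replicate number. Total counts ranged from 13109362 to 14748156, and the self-test below shows what this depth and spread can detect when few genes change. Replicates were compared by a chi-square test of counts over genes with at least 20 counts in the pair: the statistic per degree of freedom was 1.88 to 3.56 within groups and 122 to 132 between groups, so no 2 libraries agreed within sampling noise. Each library was counted as a replicate, although this test cannot tell separate cultures from separate libraries of the same RNA.

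The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 13504 genes holding at least 99.9% of counts in each library, and 5737 genes had no count in any library. Libraries were scaled by TMM, dispersions were estimated with a group design, and MYCi361 was compared with DMSO by the quasi-likelihood F test (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of F. A log2 fold change of at least 1 in size was called at least 2-fold. CPM values are scaled by the TMM library sizes unless said otherwise.

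Before the data were examined, 32 gene lists with 1005 member entries were written from general knowledge, along with the tests, the alternatives and the rule for named genes. Each member entry was found in the files under a current or older symbol. Of the 32 lists, 29 had at least 3 tested members and were compared with all other tested genes by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 29 lists. An estimated correlation and fry, which tests whether a list's genes move on balance in a direction without comparing them with other genes, were alternatives. At the preset correlation 21 lists passed, 10 up and 11 down, and 11 passed with an estimated correlation. Adjusted over the list alone, the count of called members differed from that over all genes in 4 lists, by 1 member in each. Some named genes are in 2 lists: CDKN1A and GADD45A (MYC-repressed and p53), NDRG1 (MYC-repressed and hypoxia), HK2 (MYC targets and hypoxia), MXI1 (MYC network and hypoxia), SLC2A1 (glycolysis and hypoxia), ATF3 (ATF4 and immediate early), IER3 (NF-κB and immediate early), SLC7A5 (ATF4 and AHR) and NQO1 (NRF2 and AHR).

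Named genes were chosen by the rule fixed beforehand. They are the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, MYC, MAX, CDKN1A and CD274, for each list past the camera threshold the 3 members with the smallest p in the list's direction and the 1 with the smallest p in the other direction if called, and for each other list the member with the smallest p. The values of 1 gene selected by this rule are not reported here. Exact intervals of a ratio of counts use the Clopper-Pearson method at 95% and cover counting error only.

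The procedure was tested on simulated data drawn from the 13504 genes' means, library sizes and dispersions for the comparison of MYCi361 with DMSO, with 200 changed genes. Of 50 genes changed at each size, 25 were recovered at 1.2-fold, 33 at 1.5-fold, 48 at 2-fold and 49 at 4-fold. Of 161 calls, 6 were false. In the data 9763 genes were called, so the p-value needed to pass was less strict there. These shares therefore do not carry over to the data. None of the test's 200 random lists of 40 genes passed camera at an unadjusted p of 0.05 (0 lists). Genes were simulated independently, so this cannot show whether the preset correlation is enough for lists whose genes move together. Alternatives were DESeq2 size factors, total counts without TMM, no filter, a filter of 1 CPM in 3 libraries, a replicate block, DESeq2 1.42.0, limma voom, a robust quasi-likelihood fit, leaving out each library, and for lists an estimated correlation, ranks and fry. Transcript length and GC content for a check of the lists came from the longest transcript per gene name in GENCODE 29, which matched 12662 (93.8%) of tested genes.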

Results

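RNA was measured in PC3 cells, a human prostate cancer cell line that the submitters describe as having a high level of endogenous MYC. MYCi361 is a small-molecule inhibitor of the transcription factor MYC. There were 3 libraries from cells given 6 µM MYCi361 in DMSO for 24 h and 3 libraries from cells given DMSO. Each library was made from 50 ng of total RNA with an exome-capture kit. The libraries held 13819994, 14748156 and 14725035 counts for DMSO replicates 1, 2 and 3, and 13664901, 14446506 and 13109362 counts for MYCi361 replicates 1, 2 and 3. Between 17015 and 17237 of the 25369 listed genes had at least 1 count in a library. The design gave a single comparison, MYCi361 against DMSO, which asks whether the inhibitor changes MYC target genes and which other genes change with it. Expression is given as CPM, counts scaled to the size of the library, as mean ± SD of 3 libraries per group, and folds come from the fitted log2 fold change.

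MYCi361 was followed by a broad change of the PC3 transcriptome in which cell cycle and heat shock genes fell and genes of the ATF4, unfolded protein and NRF2 responses rose. Histone, mitotic and DNA replication genes fell with list medians of -1.93, -1.77 and -1.67 on the log2 scale. Genes of the ATF4 amino acid stress response rose with a median of 1.96. MYC target genes fell by a smaller amount, with a median of -0.41, while MYC mRNA itself was 1.31-fold higher. Of 13504 genes tested, 9763 (72.3%) passed an adjusted p of 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), 4908 of them higher and 4855 lower with MYCi361. At least 2-fold changes were found for 1084 genes that rose and 1046 that fell, and 5183 of the calls were smaller than 1.5-fold. The groups did not overlap for 73.3% of tested genes, where chance gives 10%. Libraries of a group were close to each other: the common dispersion corresponded to a biological coefficient of variation of 3.24%, and the first principal component separated the groups with 88.2% of the variance. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. The 108 genes selected by the rule fixed beforehand had an adjusted p of 0.000559 or less by edgeR, except CD274 at 0.00937. Apart from MYC, MAX, CDKN1A and CD274, the rule picks genes by their p or by their fold. Those picked by fold had already passed the threshold with no overlap between groups. That the picked genes passed the threshold is therefore no separate result.

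**Figure D1:**
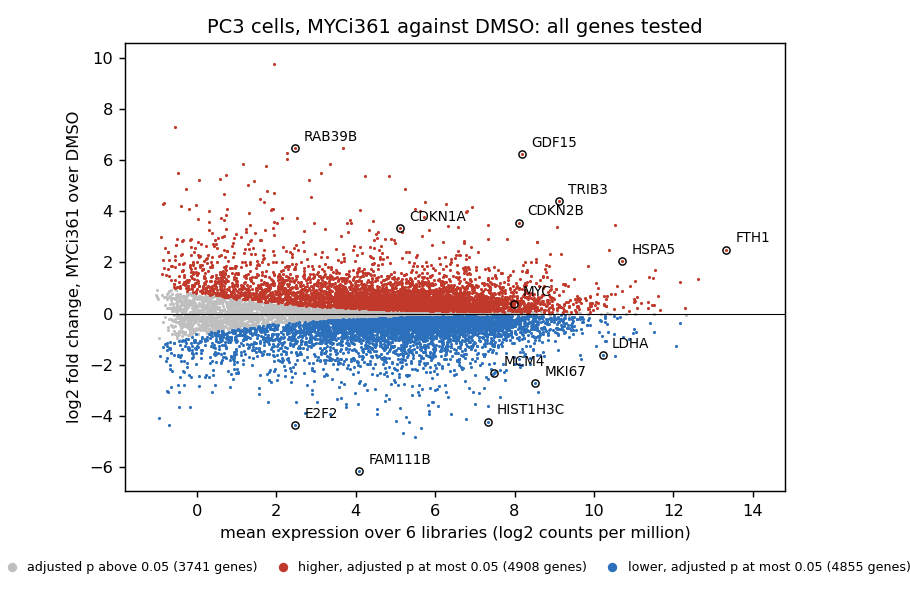
Each point is one of 13504 tested genes, with the mean expression of the 6 libraries in log2 CPM on the x axis and the log2 fold change of MYCi361 over DMSO on the y axis. Red and blue points passed an adjusted p of 0.05 (4908 higher, 4855 lower), grey points did not, and circled genes are named, from FAM111B at -6.14 to RAB39B at 6.48. The highest point, KLHDC7B, had 0 counts in DMSO, so its position depends on the prior count.

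MYC transcript was higher, not lower, after 24 h of MYCi361, rising 1.31-fold from 219 ± 9.72 to 286 ± 6.48 CPM (log2 fold change 0.39 ± 0.036 SE, adjusted p = 4.57e-14 by edgeR). Its obligate partner MAX rose 1.41-fold from 71.8 ± 4.9 to 102 ± 1.95 CPM. Of the MAX-binding repressors that compete with MYC, MXD1 was 6.32-fold higher (from 6.82 ± 0.512 to 43.2 ± 2.77 CPM), MXI1 2.33-fold higher (from 19.2 ± 0.203 to 44.6 ± 0.527 CPM) and MNT 1.89-fold higher (from 36.5 ± 2.12 to 68.9 ± 2.999 CPM). MXD4 rose 1.26-fold and MGA, at 1.06-fold, did not pass, and these 2 were added after their values were seen. MXD3, the family member expressed in proliferating cells, fell 4.7-fold from 8.48 ± 1.35 to 1.8 ± 0.1005 CPM. Over the MYC network list, 7 of 13 members rose, 3 fell and 3 did not pass (camera adjusted p = 0.0392). That list call was lost in camera with an estimated correlation between genes (adjusted p = 0.141). The estimate, -0.034, lay below the preset correlation, so correlation between the members does not account for the loss.

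**Figure D2:**
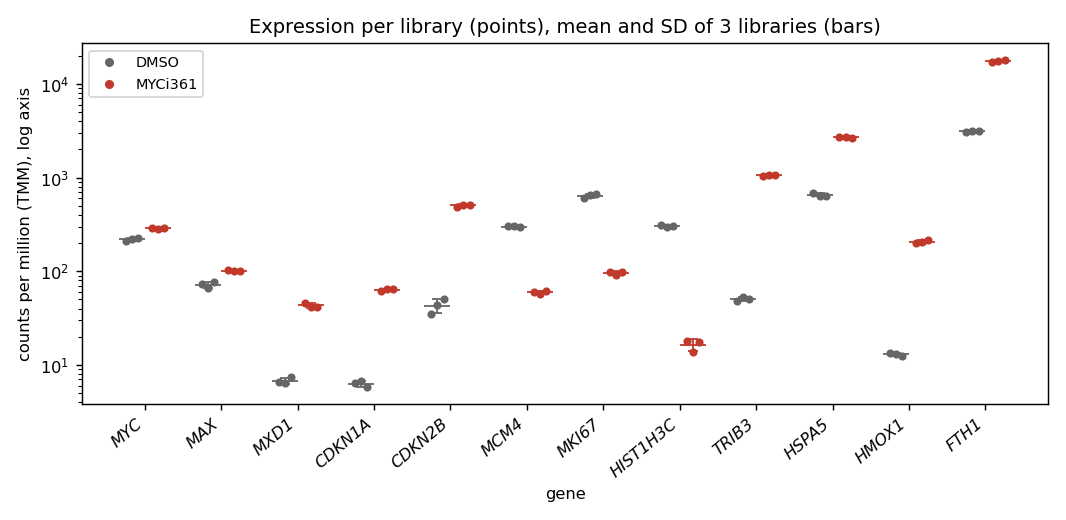
Expression of 12 genes in CPM on a log axis, with a point per library and the mean and SD of 3 libraries as bars, DMSO in grey and MYCi361 in red. MYC and MAX are slightly higher with MYCi361, MCM4, MKI67 and HIST1H3C are lower, and the other genes are higher, with no overlap between groups in the 12 genes shown.

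MYC target genes fell as a group. Of the 57 members of the list, 39 fell, 6 rose and 12 did not pass, with a median log2 fold change of -0.41 (quartiles -0.86 and -0.041). Adjusted over the list alone, 39 fell and 7 rose. The list was lower than other genes (camera adjusted p = 1.36e-06 with the preset correlation, 0.0221 with an estimated one). The members that fell with the smallest p were MCM4, a subunit of the replicative helicase, which fell 5.02-fold from 299 ± 3.22 to 59.7 ± 2.34 CPM, UNG, a uracil-DNA glycosylase, which fell 4.67-fold from 103 ± 7.32 to 22.1 ± 1.63 CPM, and the mitotic kinase PLK1, which fell 2.97-fold from 164 ± 5.6 to 55 ± 2.56 CPM. HK2, the hexokinase that starts glycolysis, went the other way and rose 1.43-fold from 198 ± 4.02 to 284 ± 7.64 CPM. Without 9 members (7 with cell cycle, DNA repair or metabolic roles, and the chaperones HSPD1 and HSPE1), the other 48 still lay lower, with a median of -0.31 (31 lower, 5 higher, camera adjusted p = 4.41e-05).

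Ribosome genes split in direction. Genes of ribosome biogenesis outside the MYC target list fell in 41 of 60 cases and rose in 5, with a median of -0.27 (camera adjusted p = 2.55e-05). The list call was lost with an estimated correlation (adjusted p = 0.0777). The nucleolar protein NCL fell 1.74-fold from 1857 ± 25.5 to 1067 ± 31.9 CPM, the RNA polymerase I factor UBTF fell 1.71-fold from 433 ± 14.1 to 254 ± 5.06 CPM and the RNA acetyltransferase NAT10 fell 1.9-fold from 189.9 ± 5.59 to 100.1 ± 3.48 CPM, whereas the helicase DDX10 rose 1.42-fold. Structural proteins of the cytosolic ribosome rose in 68 of 75 cases, by a small and even amount (median 0.32, quartiles 0.21 and 0.40). RPL10 rose 1.56-fold, RPL13 1.47-fold and RPL28 1.41-fold, while RPS26 fell 1.24-fold. Camera gave an adjusted p of 7.36e-13 for this list, which was lost at an adjusted p = 0.247 with an estimated correlation. Many of these genes have processed pseudogenes, and how reads shared with them were counted is not given in the sources used here.

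Genes described as repressed by MYC mostly rose, with 11 of 15 tested members higher and 3 lower. The cyclin-dependent kinase inhibitor CDKN2B (p15) rose 11.8-fold from 42.9 ± 7.37 to 506 ± 13 CPM, and CDKN1A (p21) rose 10.1-fold from 6.3 ± 0.488 to 63.6 ± 1.33 CPM. NDRG1, a stress-induced growth suppressor, rose 4.999-fold from 192 ± 12.4 to 962 ± 23.8 CPM, and GADD45A, a growth arrest gene, rose 4.91-fold from 33.6 ± 0.981 to 165 ± 8.42 CPM. CCND1, which encodes the G1 cyclin D1, fell 3.38-fold from 1263 ± 21.2 to 373 ± 12.3 CPM. The list passed camera (adjusted p = 0.00666), and the call was lost with an estimated correlation (adjusted p = 0.141).

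The cell cycle program fell in nearly every member. Each of the 60 mitotic genes fell, 57 of them at least 2-fold: MKI67, the proliferation marker Ki-67, fell 6.63-fold from 637 ± 27.7 to 96.1 ± 4.36 CPM, the kinetochore protein CENPF fell 3.94-fold and the cytokinesis scaffold ANLN fell 4.86-fold. Of 51 replication genes, 50 fell, among them the ribonucleotide reductase subunit RRM2 (9.67-fold, from 361 ± 7.04 to 37.3 ± 1.2 CPM), UHRF1, a maintenance factor of DNA methylation (8.45-fold), and the helicase subunit MCM3 (5.14-fold). The replication factor C subunit RFC1 rose 1.32-fold. Each of 21 tested replication-dependent histone genes fell, with HIST1H1D 8.57-fold, HIST1H2AE 7.4-fold and HIST1H3D 12.1-fold lower. Histone genes are near-identical copies, so the value of a single histone gene is uncertain where reads were shared. Camera adjusted p was 1.23e-31 for mitosis, 2.59e-21 for replication and 3.76e-17 for histones, and 0.0221, 0.0112 and 0.0221 with an estimated correlation.

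The lists of the ATF4, unfolded protein, NRF2 and lysosome responses rose. In the ATF4 list, which covers the integrated stress response, 39 of 41 members rose, 37 at least 2-fold, and the other 2 did not pass (camera adjusted p = 2.09e-28, 0.0111 with an estimated correlation). The stress cytokine GDF15 rose 75-fold from 7.64 ± 0.672 to 574 ± 9.89 CPM, the pseudokinase TRIB3 rose 20.8-fold from 50.9 ± 2.15 to 1062 ± 12.7 CPM, and PPP1R15A, which directs dephosphorylation of eIF2α, rose 7.03-fold from 94 ± 0.206 to 661 ± 6.53 CPM. Endoplasmic reticulum chaperone and unfolded protein response genes rose in 27 of 29 cases (median 0.65, camera adjusted p = 1.79e-13, 0.0423 with an estimated correlation). The chaperone HSPA5 (BiP) rose 4.11-fold from 658 ± 28.4 to 2705 ± 31 CPM, the stress sensor ERN1 (IRE1α) rose 10.8-fold from 13.5 ± 0.241 to 146 ± 4.51 CPM, and HERPUD1, a factor of ER-associated degradation, rose 5.34-fold. NRF2 target genes rose in 26 of 29 cases and fell in 2 (median 0.70, camera adjusted p = 5.08e-09, 0.049 with an estimated correlation). The iron storage subunits FTH1 and FTL rose 5.66-fold and 3.59-fold (FTH1 from 3105 ± 31.7 to 17577 ± 524 CPM), and the heme-degrading enzyme HMOX1 rose 15.8-fold from 13.1 ± 0.486 to 206 ± 7.27 CPM, while the carbonyl reductase CBR1 fell 1.18-fold. FTH1, FTL and the chaperone gene HSP90AA1 have processed pseudogenes, so reads shared with them leave their values uncertain. Lysosome and autophagy genes rose in 35 of 52 cases and fell in 3, or 5 when scaled by total counts (median 0.44, camera adjusted p = 3.5e-08, 0.0221 with an estimated correlation). The autophagy receptor SQSTM1 (p62) rose 5.64-fold from 398 ± 3.89 to 2246 ± 39.1 CPM, WIPI1 rose 6.97-fold and MAP1LC3B rose 3.23-fold, while the proton pump subunit ATP6V1A fell 1.41-fold.

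Cytosolic folding and degradation genes went the other way. Heat shock genes fell in 15 of 19 cases and rose in 3 (median -0.70, camera adjusted p = 1.78e-06, 0.0221 with an estimated correlation). The chaperone HSP90AA1 fell 2.4-fold from 6013 ± 103 to 2504 ± 39.6 CPM, the co-chaperones DNAJA1 and STIP1 fell 2.19-fold and 1.88-fold, and DNAJB4 rose 3.1-fold. Proteasome subunits fell in 24 of 31 cases with a median of -0.34 (camera adjusted p = 2.07e-05), a call lost at an adjusted p = 0.204 with an estimated correlation. PSMD1 fell 1.63-fold, PSMD12 1.54-fold and PSMD2 1.37-fold, and PSMD8 rose 1.1-fold.

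Metabolic genes fell in most lists. Nucleotide synthesis genes fell in 22 of 31 cases and rose in 5 (median -0.83, camera adjusted p = 2.07e-05, 0.049 with an estimated correlation). The thymidine kinase TK1 fell 3.35-fold, the ribonucleotide reductase subunit RRM1 2.95-fold and the thymidylate synthase TYMS 5.26-fold, whereas SHMT2, the mitochondrial enzyme that draws carbon units from serine, rose 2.78-fold from 179 ± 2.24 to 499 ± 5.96 CPM. Glycolysis genes fell in 18 of 21 cases (median -0.47, camera adjusted p = 9.63e-07, 0.0221 with an estimated correlation). The lactate dehydrogenase LDHA fell 3.05-fold from 1798 ± 89.5 to 589 ± 4.55 CPM, PGK1 2.11-fold and PKM 1.66-fold, and the glucose transporter SLC2A1 rose 1.33-fold. Nuclear genes of the respiratory chain fell in 47 of 64 cases with a median of -0.25 (camera adjusted p = 3.15e-05), a call lost at an adjusted p = 0.283 with an estimated correlation. SDHA, the catalytic subunit of succinate dehydrogenase, fell 2.79-fold, the ATP synthase subunits ATP5A1 and ATP5G3 fell 1.59-fold and 2.12-fold, and NDUFS4 of complex I rose 1.44-fold. The lists of cholesterol synthesis (13 of 26 lower, 6 higher or 3 higher by total counts or DESeq2, camera adjusted p = 0.0573) and fatty acid synthesis (12 of 18 lower, 5 higher, adjusted p = 0.107) did not pass, although cholesterol synthesis passed without DMSO replicate 1 (camera adjusted p = 0.0484) and without MYCi361 replicate 2 (adjusted p = 0.0398). In the fatty acid list the member with the smallest p was ACLY, which supplies cytosolic acetyl-CoA and fell 1.61-fold.

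Inflammatory and signalling genes were mixed. Of the NF-κB and cytokine list, 14 of 25 members rose and 4 fell (camera adjusted p = 0.00666, lost at an adjusted p = 0.0879 with an estimated correlation). That estimate, 0.0074, was below the preset correlation. The neutrophil-attracting chemokines CXCL8 and CXCL2 rose 9.66-fold and 11.6-fold, from 10.8 and 2.35 CPM, IER3 rose 2.46-fold, and the NF-κB subunit NFKB1 fell 1.52-fold. Immediate early genes rose in 18 of 30 cases and fell in 8 (adjusted p = 0.00652, lost at an adjusted p = 0.204 with an estimated correlation), with ATF3 (also in the ATF4 list) 29.4-fold and the ERK phosphatase DUSP5 3.29-fold higher and the ERK pathway inhibitor SPRY4 4.82-fold lower (from 352 ± 11.5 to 73 ± 6.08 CPM). Of 6 tested targets of the aryl hydrocarbon receptor, 5 rose (adjusted p = 0.00395, lost at an adjusted p = 0.0777 with an estimated correlation), among them the aldehyde dehydrogenase ALDH3A1 at 5.96-fold. The estimate for the receptor's targets, -0.13, was also below the preset correlation. The amino acid transporter SLC7A5 (2.87-fold) and the quinone reductase NQO1 (1.62-fold) also belong to the ATF4 and NRF2 lists, and the receptor's repressor AHRR fell 1.33-fold. Interferon-stimulated genes rose in 13 and fell in 15 of 37 cases (adjusted p = 0.919), OAS3 falling 3.5-fold. Antigen presentation and checkpoint genes rose in 8 and fell in 6 of 20 cases (adjusted p = 0.444, median 0.081, mean -0.013, camera direction up). HLA-C, a class I heavy chain with close paralogs, was 1.79-fold higher. CD274, which encodes PD-L1, was low and fell 1.54-fold from 3.78 ± 0.392 to 2.47 ± 0.469 CPM, on 166 counts in DMSO and 100 with MYCi361 over 3 libraries each (log2 fold change -0.62 ± 0.22 SE). Its call was lost without DMSO replicate 3 (adjusted p = 0.0539 by edgeR) and without MYCi361 replicate 2 (adjusted p = 0.0711).

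The lists of p53 targets, hypoxia and epithelial and mesenchymal state did not pass. Targets of p53, a factor that PC3 cells lack in functional form, rose in 9 and fell in 8 of 25 cases (camera adjusted p = 0.324), with GADD45A having the smallest p. Hypoxia response genes rose in 13 and fell in 8 of 25 cases (adjusted p = 0.109), led by NDRG1. Epithelial and mesenchymal genes rose in 13 and fell in 9 of 26 cases (adjusted p = 0.626), with the membrane protease MMP14 1.86-fold higher. Among markers of other cells, 4 of 8 tested markers of androgen-responsive luminal cells fell and 1 rose (adjusted p = 0.107), the homeobox gene HOXB13 falling 3.92-fold from 529.6 ± 15.3 to 135 ± 1.61 CPM. The tested fibroblast markers COL1A1, PDGFRA and COL3A1 fell 5.21-fold, 3.95-fold and 6.38-fold (camera adjusted p = 0.00666, lost at an adjusted p = 0.0879 with an estimated correlation). Their estimate, -0.23, was below the preset correlation. Of 2 tested leukocyte markers, both rose, with the lysosomal glycoprotein CD68 2.52-fold higher, and of 2 tested endothelial markers the receptor KDR fell 4.59-fold and the other did not pass. No erythroid marker had enough counts to be tested.

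**Figure D3:**
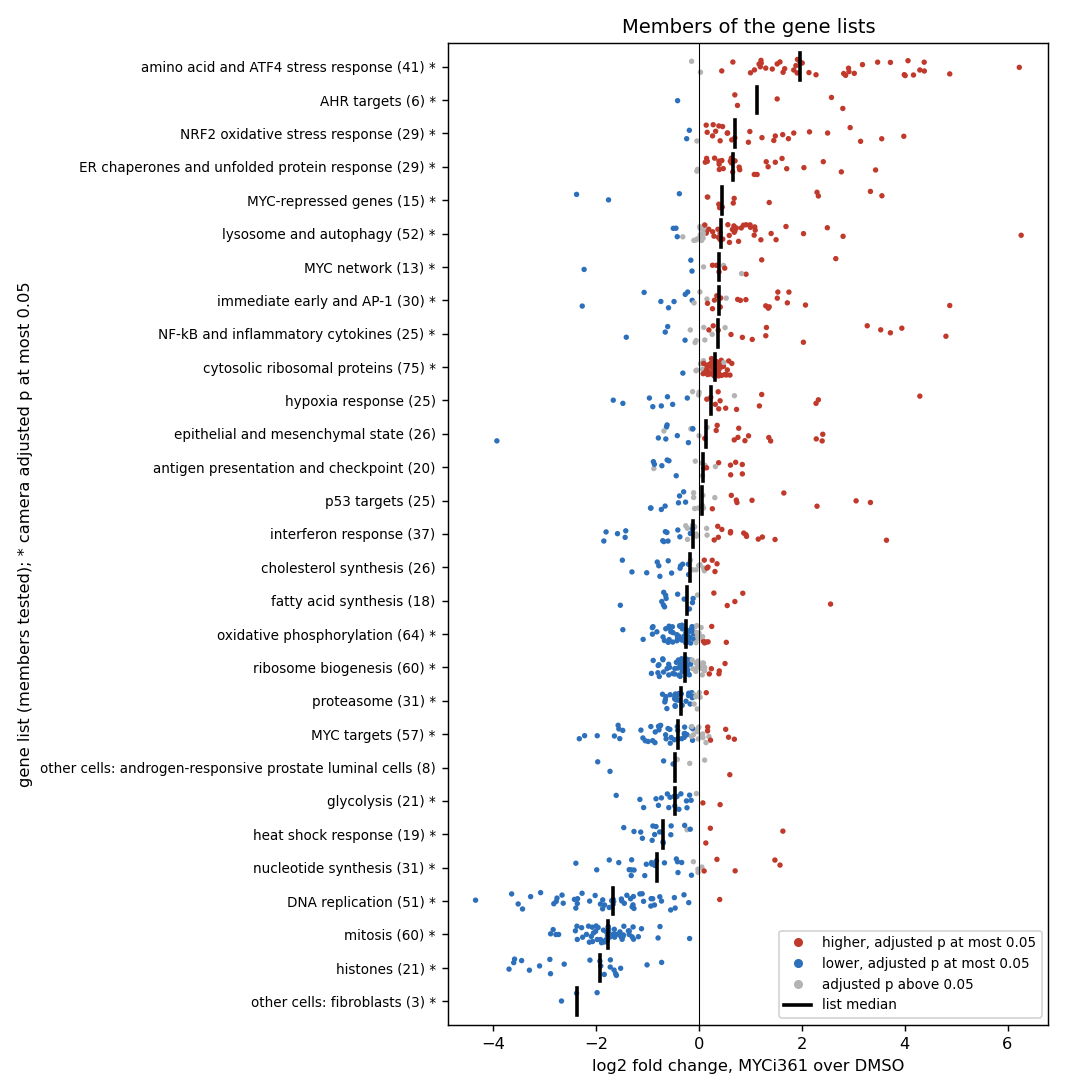
Log2 fold change of MYCi361 over DMSO (x axis) for each tested member of the 29 lists with at least 3 tested members (rows, number of members in brackets), with black bars at the list medians. Medians run from -2.38 for the 3 fibroblast markers, -1.93 for histones and -1.77 for mitosis up to 1.96 for the ATF4 list. Asterisks mark lists with a camera adjusted p of at most 0.05 at the preset correlation.

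Among genes with a mean of at least 5 CPM, the 10 largest increases were in RAB39B, LOC344887, GDF15, STK32A, S100P, RPLP0P2, HKDC1, BEX2, ATF3 and IL20RB, with log2 fold changes from 6.48 to 4.55. RAB39B, a small GTPase, went from 5 counts over the DMSO libraries to 446 over the MYCi361 libraries, a depth-adjusted ratio of 96.2 (95% exact interval 40.9 to 298, counting error only). HKDC1, a hexokinase-like enzyme, rose from 1.34 ± 0.0636 to 55.9 ± 2.18 CPM. The calcium-binding protein S100P rose from 0.368 ± 0.119 to 17 ± 1.04 CPM and the cytokine receptor chain IL20RB from 0.59 ± 0.156 to 14 ± 1.68 CPM. The kinase STK32A rose from 0.346 ± 0.19 to 20.03 ± 0.878 CPM. BEX2 rose from 0.365 ± 0.0331 to 13.8 ± 0.744 CPM and the locus LOC344887 from 0.273 ± 0.113 to 25.2 ± 1.64 CPM. RPLP0P2 rose from 0.869 ± 0.308 to 36.7 ± 0.502 CPM, and as a pseudogene of RPLP0 its count is uncertain, although RPLP0 itself rose only 1.27-fold. The 10 largest decreases were in FAM111B, E2F2, NPY1R, LINC00261 and the histone genes HIST1H2BM, HIST1H2AL, HIST1H2AB, HIST1H3C, HIST1H2AH and HIST1H2BB. The replication-associated protease FAM111B fell 70.5-fold from 33.6 ± 2.49 to 0.471 ± 0.105 CPM, the cell cycle factor E2F2 fell 20.3-fold from 10.7 ± 1.06 to 0.52 ± 0.166 CPM, the neuropeptide Y receptor NPY1R fell 18.3-fold from 61 ± 2.43 to 3.31 ± 0.418 CPM and the long non-coding RNA LINC00261 fell 17.2-fold from 207 ± 7.76 to 12 ± 0.115 CPM. The 6 histone genes had log2 fold changes between -4.83 (HIST1H2BM) and -4.05 (HIST1H2BB), with HIST1H2AL at -4.67, HIST1H2AB at -4.46, HIST1H3C at -4.22 and HIST1H2AH at -4.22. Some abundant non-coding entries moved with the treatment too: MALAT1 was 3.29-fold higher and MIR3648 2.56-fold higher with MYCi361. The non-coding RMRP rose less, from 4546 to 4730 CPM by total counts in DMSO libraries to 5224 to 5481 CPM with MYCi361. The 20 most abundant genes, coding and non-coding, took 8.93 to 9.26% of counts with MYCi361 against 6.08 to 6.44% in DMSO. They include the coding gene FTH1, which rose from 3105 to 17577 CPM. All values are relative to the TMM-scaled size of each library, or to its total where said, so a change in RNA per cell was not measured.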

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

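The alternatives below were chosen before the data were examined. No result changed direction past its threshold. The number of genes changed by MYCi361 was 9763 and ranged from 8960 (DESeq2 test) to 9972 (no filter), with 9313 to 9569 when a library was left out, and the number of genes changed at least 2-fold by MYCi361 was 2130 and ranged from 2025 (1 CPM filter) to 2485 (no filter), with 2208 to 2243 when a library was left out. The share of calls that were higher was 50.3%, and 46.9% when libraries were scaled by total counts, which moved the median of all genes from 0.010 to -0.028. MYC stayed higher, with log2 fold changes from 0.35 to 0.42, and the MYC target list stayed lower, with adjusted p from 6.03e-09 (no filter) to 0.0221 (estimated correlation). The other 28 tested lists held 20 calls, which became 10 with an estimated correlation and 27 with fry. Higher correlation does not account for every loss. The estimate lay below the preset 0.01 for NF-κB and cytokines (0.0074), MYC network (-0.034), AHR targets (-0.13) and fibroblast markers (-0.23). The others that lost the call had estimates from 0.033 to 0.52. The ATF4 list, at 0.012, went from 2.09e-28 to 0.0111 in camera adjusted p. Camera with an estimate was therefore stricter even at a similar correlation, for a reason not tested. The lists that lost their call with an estimated correlation were MYC-repressed genes, MYC network, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, NF-κB and cytokines, immediate early genes, AHR targets, proteasome and fibroblast markers, and their adjusted p with it stood between 0.0777 and 0.283. The fibroblast markers also lost it without a filter (0.0557). Cholesterol synthesis, at 0.0573, passed with total counts (0.0493), with no filter (0.0225), without DMSO replicate 1 (0.0484) and without MYCi361 replicate 2 (0.0398). Fry also passed cholesterol synthesis, fatty acid synthesis, hypoxia, p53 targets, antigen presentation and checkpoint, epithelial and mesenchymal state and the luminal markers (adjusted p from 8.77e-06 to 0.00488). CD274 lost its call without DMSO replicate 3 and without MYCi361 replicate 2, and the other named genes kept theirs under every alternative of the gene test. Small counts within lists moved by over 1.5 times without single libraries: called AHR targets that fell went from 1 to 2 (without DMSO replicate 1, MYCi361 replicate 1 or MYCi361 replicate 3), called glycolysis genes that rose from 2 to 1 (without DMSO replicate 2 or MYCi361 replicate 3) and ribosomal protein genes that fell from 1 to 2 (without DMSO replicate 3). With total counts, ribosomal protein genes that fell went from 1 to 3, lysosome and autophagy genes that fell from 3 to 5, cholesterol synthesis genes that rose from 6 to 3 (also 3 with the DESeq2 test) and glycolysis genes that rose from 2 to 1. The replicate numbers did not pair the libraries: over 10061 genes the deviations of libraries with the same number correlated at -0.0045, -0.037 and 0.070, and a replicate block gave 9754 changed genes and changed no call of a list or named gene. Low counts limited CD274 and the genes near 0 in DMSO. In the self-test, where few genes changed, 25 of 50 genes changed 1.2-fold were found.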

Other observations

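The scans of symbol stems and tRNA synthetases, the tests on entries linked to the ribosomal RNA precursor, and the regroupings of libraries were tests chosen after the results were seen, and the removal of 9 MYC targets was fixed earlier but its use to weigh an explanation was not. Some gene families were also scanned by the start of their symbols, and these overlap the fixed lists in part. Among 169 symbol stems with at least 10 tested genes, 10 passed camera at the preset correlation, including the stems HIST, MCM, RPL and RPS, which overlap the fixed lists in part. The NUP stem, mostly nuclear pore genes, fell in 19 of 21 cases, with NUP188 at -1.41 and NUP210 at -1.13 on the log2 scale, and the SR splicing factors (SRSF) fell in 10 of 11, with SRSF2 at -1.76 and SRSF1 at -1.23. The CCT stem, mostly the cytosolic chaperonin, fell in 7 of 10 cases, with CCT5 at -0.91, and DEAH-box helicases (DHX) in 13 of 15, with DHX15 at -1.30. The SEC stem, largely factors of protein translocation and vesicle coats, rose in 15 of 26 cases, with SEC24D at 1.48 and SEC31A at 1.12, and Krüppel-like factors (KLF) rose in 9 of 11, with KLF13 at 1.66 and KLF6 at 1.37. Of these stems, SEC24D and SEC61B are also in the unfolded protein response list, and KLF2, KLF4, KLF6 and KLF10 are in the immediate early list, KLF6 also in the MYC-repressed list. Camera adjusted p was 4.00e-05 for NUP, 0.000563 for SRSF, 0.00229 for SEC, 0.00395 for KLF, 0.0252 for DHX and 0.0263 for CCT. With an estimated correlation no stem passed (camera adjusted p of 0.48 or more). The HIST stem, with 48 of 49 genes lower and a median of -2.96, did not pass it either. That version therefore does not tell stems that shift from stems that do not.

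Cytosolic and mitochondrial tRNA synthetases were compared. Of 20 cytosolic genes 13 rose and 4 fell (median 0.71), with WARS at 1.88, and of 17 mitochondrial genes 2 rose and 10 fell (median -0.25), with LARS2 at -1.26. A two-sided permutation test over genes, which are not independent replicates, gave p = 9e-05 for the difference of means. GARS and KARS, counted as cytosolic, also encode the mitochondrial enzymes, so the contrast is not clean. The ATF4 list holds 8 of the cytosolic genes. The other 12 had a median of 0.025 (5 higher, 4 lower), and the same permutation test against the mitochondrial genes gave p = 0.0137. KLHDC7B and BHMT were the 2 called genes with no count in any DMSO library: against a floor of 3 counts over that group they were at least 112.5-fold and at least 20.1-fold higher (313 and 56 counts with MYCi361).

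The first pattern weighed is the fall of MYC target genes (median -0.41, 95% bootstrap interval over genes -0.64 to -0.23). A trend with transcript length and GC content is argued against, since the median after removing it was -0.45 (-0.65 to -0.25), and a general fall of genes at this expression level is argued against by 10000 random lists matched on expression, the central 95% of which reached down to -0.20. The 9 members with cell cycle, metabolic or chaperone roles did not carry it alone, as the other 48 had a median of -0.31 (-0.56 to -0.15). What stays open is whether the fall may follow loss of MYC activity or the fall in proliferation and the stress response seen in the same libraries. A single dose and time hold these together. MYC mRNA was not lower, but its level does not show the activity of the MYC protein, which was not measured here.

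The second pattern is the small rise of cytosolic ribosomal protein genes (median 0.32, interval 0.27 to 0.35) beside a fall of ribosome biogenesis genes (median -0.27, interval -0.36 to -0.21). Length and GC content left 0.26 (0.22 to 0.31) of the rise, and the central 95% of random lists matched on expression reached up to 0.15. The intervals and random lists treat genes as independent. Members of the ribosomal protein list are correlated, so these ranges are too narrow and do not settle either explanation. The members shift as a block between libraries (estimated correlation 0.52), and camera with that correlation did not pass, yet the lowest MYCi361 library mean lay 0.21 above the highest DMSO mean on the log2 scale, against ranges of 0.12 within DMSO and 0.026 within MYCi361. This gap goes against the prediction for a shift of the list between libraries without regard to treatment. It does not settle that explanation, because chance leaves no overlap between 3 and 3 libraries in 10% of cases. Reads shared with pseudogenes were not tested.

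The third pattern is the rise of MIR3648, MIR3687, LOC284801 and MIR663A, which lie in sequence resembling the ribosomal RNA precursor or ribosomal RNA. They rose 2.56, 2.65, 2.36 and 2.70-fold, a span of 0.20 on the log2 scale. The gap between the groups' library means was 0.97 and the range within DMSO 0.48. The entries were picked because they rose, which can narrow the span and fixes the gap. The span therefore does not decide whether they share a source of reads, and the gap decides nothing on carry-over. Carry-over of ribosomal RNA, whether or not it follows the treatment, and a treatment effect on precursor RNA all stay open.

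Regrouping the 6 libraries gave 10 splits of 3 against 3, too few for a share under 0.05. The real split had the largest count in each case (1 of 10 splits): 9763 changed genes against a highest other of 0, 2130 genes changed at least 2-fold against 0, and 21 lists past the camera threshold against 18. Each other split puts 2 libraries of a treatment with 1 of the other, so the treatment difference counts as spread within its groups. The gene counts of 0 follow from this mixing. Part of the treatment difference also stays between the mixed groups, so none of these counts is a baseline for chance.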
